A study of Mus musculus with 6 samples.

How the data were processed

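RNA of cultured mouse cells labelled as lymphatic endothelial cells was analysed in 6 libraries, 3 controls and 3 exposed to red blood cells, each for 24 h. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) kit. The submitters' processing notes name the mouse build GRCm39; the aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. No column of another sample was used.

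The authors deposited 2 tables of the same 15528 gene symbols. The first holds raw counts per gene, deposited as whole numbers without normalization. The second holds FPKM values, and their ratio to the counts showed that the authors scaled each library by the sum of its counts over the listed genes (largest relative departure 4.7e-07 over 12251 genes). Both tables therefore describe the same reads and are no independent check of each other. Genes are named by the symbols of the tables; no coordinates are printed because the reference used here is of another build than GRCm39. It gave only transcript GC content, matched by symbol for 98.1% of the tested genes, and symbol synonyms for list members. Gene model length was computed from the 2 tables (median 3390 bases).

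Total counts were 17263359, 18381419 and 17841554 in control replicates 1 to 3 and 18000112, 18327247 and 18009450 in treated replicates 1 to 3. At these depths 3 counts over the 3 libraries of a group correspond to 0.056 CPM in the controls, the floor against which genes with 0 counts in a group are compared. Where a group had 1 to 3 counts, the ratio is given with its exact (Clopper-Pearson) 95% interval. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. The 10 genes with the most counts held 3.83% to 4.46% of a library.

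Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11208 genes with 99.96% of the counts. Libraries were scaled by TMM, dispersions were estimated with the group as the design, and glmQLFit and glmQLFTest gave two-sided p-values, adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. CPM values are scaled to the total of all listed counts of a library and given with the SD over 3 libraries, and standard errors are those of the log2 fold change. Of 28 gene lists, 26 had at least 3 tested members and were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it. FPKM were tested with limma's trend method on log2(FPKM + 1) for genes with a mean of at least 1 FPKM in either group.

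The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, among called genes of at least 10 CPM whose libraries do not overlap between groups, the 12 largest rises and 12 largest falls. From all called genes it takes the 5 smallest p-values in each direction, and from each list up to 4 tested members in order of p, with the 3 highest members by CPM for lists of other cell types. It named 121 genes, of which the text gives those that were called and some others. The lists cover lymphatic endothelial identity, pan-endothelial genes, heme and iron handling, NRF2 targets, inflammatory cytokines and chemokines, leukocyte adhesion, NF-kB feedback, interferon response, antigen presentation, complement and acute phase, p53 targets, ATF4 targets, unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, S phase, G2 and mitosis, extracellular matrix and TGF-beta targets, lymphangiogenic ligands, lysosome and engulfment, immediate early genes and the mitochondrial genome, and as markers of other cell types erythroid cells, leukocytes, platelets, fibroblasts and mural cells, and epithelial and mesothelial cells.

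Alternatives were RLE scaling, no scaling beyond library size, DESeq2 1.42.0, limma voom, no filter, a filter of 1 CPM in 3 libraries, leaving the erythroid genes out before scaling, the replicate number as a block, leaving out each library in turn, and for FPKM a pseudocount of 0.1 and no filter. In each fit with a library left out the low-count filter was rerun, so the tested genes and list members can differ. Voom with library quality weights and an offset from each library's trend with gene length and GC content were added after control replicate 2 was seen to stand apart. The pipeline was tested on simulated counts for the real genes with 200 changed genes; the simulation was revised once to add a shifted list, and the values are from that draw. With 6 libraries and 11208 genes it called 41.8% of 67 genes changed 1.25-fold, 88.1% of 67 changed 1.5-fold and 95.5% of 66 changed 2-fold in the right direction, and 3.68% of all calls were unchanged genes. The simulated libraries shared the same dispersion for each gene and held no outlying library or gene length trend. These shares may therefore not hold for the real libraries.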

Results

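Poly(A) RNA was sequenced from cultured mouse cells labelled as lymphatic endothelial cells, the cells that line lymphatic vessels. The 6 libraries formed 2 groups: 3 control libraries and 3 libraries of cells exposed to red blood cells, all taken at 24 h. The series title places the cells in a study of how the brain and the neck lymph nodes affect each other after bleeding beneath the arachnoid membrane, so the comparison asks how the transcripts of these cells differ once red blood cells are present. Total counts ranged from 17263359 in control replicate 1 to 18381419 in control replicate 2. Between 13458 and 13731 of the 15528 listed gene symbols had at least 1 count in a library. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

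Many markers of endothelial identity were missing or near 0 in both groups. Of 16 lymphatic identity markers 10 are listed and 6 were tested. Of 16 pan-endothelial markers 9 are listed and 4 were tested. In the controls Nr2f2, a regulator of venous and lymphatic identity, had 161 ± 1.38 CPM (counts scaled to the library total; SD, n = 3) and the co-receptor Nrp2 had 272 ± 52.5 CPM, whereas Flt4, the receptor of the lymphatic growth factor Vegfc, had 3.62 ± 0.73 CPM and Pecam1 had 14.98 ± 1.88 CPM. Eng held 99.3 ± 8.19 of the 119 CPM summed over the pan-endothelial list. Cdh5 had 7 counts and Kdr 0 counts over the 3 control libraries. Pdpn had 6, Tek 3, Sox18 2 and Itga9 0 counts there. Prox1 and Lyve1 are not listed in the tables used here, which hold only symbols with at least 1 count. Some transcripts typical of other cell types were abundant, with 448 ± 34.3 CPM of the keratin Krt8, 187 ± 1.96 CPM of the mesothelial marker Msln and 464 ± 25.8 CPM of the collagen gene Col1a2. Yet only 4 of 8 listed epithelial and mesothelial markers and 3 of 12 listed fibroblast and mural markers had enough counts to be tested. Krt5, Wt1 and Lum had 0 counts in the controls. The myeloid markers Csf1r and Cd68 had 25.0 ± 2.72 and 20.6 ± 1.39 CPM, while 12 of the 14 listed leukocyte markers lay under 0.5 CPM in the controls. The lymphatic endothelial identity of the cells is thus taken from the label and is not established by these levels, and neither is another identity.

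Control replicate 2 stood apart from the other libraries. Its counts differed from those of control replicates 1 and 3 by a chi-square per gene of 28.2 and 26.8, against 1.99 between these others and 1.73 to 2.13 among the 3 treated libraries. Control replicates 1 and 3 differed from the treated libraries by 5.56 to 6.38 per gene. No pair agreed within counting noise. The first principal component, with 55.7% of the variance of log2 CPM, parted the groups, and the second, with 22.6%, set control replicate 2 at -17.2 against 13.5 and 11.4 for the other controls.

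With red blood cells, hemoglobin transcripts were over 100-fold higher and chemokine, NF-kB feedback and complement genes were higher. A smaller number of genes was lower by less than 2-fold. The hemoglobin transcripts, and immune transcripts of few counts such as Cd74 and Lcn2, may have come with the added cells. These libraries cannot tell that from expression in the cultured cells. Of 11208 genes tested with edgeR's quasi-likelihood test, 164 passed a Benjamini-Hochberg adjusted p of 0.05, 130 of them higher and 34 lower with red blood cells. All 54 called genes that changed at least 2-fold by the point estimate were higher in edgeR. Genes called lower by at least 2-fold numbered 1 in DESeq2, 5 without control replicate 2, 7 with library weights in voom, and 1 each with the length and GC correction and without control replicate 1, treated replicate 1 or treated replicate 3. At an unadjusted p under 0.05 there were 1120 genes. In all 164 called genes the libraries of the 2 groups did not overlap, which held for 19.6% of all tested genes against 10% by chance. The largest rises among the 12 named by fold were those of the globins Hbb-bs (log2 fold change 7.77 ± 0.12 SE) and Hba-a1 (7.63 ± 0.11) and of Alas2, the erythroid enzyme of heme synthesis (7.51 ± 0.21). The globins Hba-a2 (7.06) and Hbb-bt (6.92) came next, followed by the chemokines Ccl2, Ccl7, Cxcl1 and Cxcl5, and then by Syt7, a calcium sensor of membrane fusion (2.58-fold), the serine protease C1s1 of the complement cascade (2.45-fold) and Prl2c2, a secreted protein of the prolactin family (2.22-fold). Reads of Hba-a1 and Hba-a2, of Hbb-bs and Hbb-bt, of Prl2c2 and Prl2c3 and of C1s1 and C1s2 can be shared between near-identical copies, so the split within each pair is uncertain. The count of calls rested on single libraries. Without control replicate 2 it was 899, with 473 higher and 426 lower. It was 72, 62 or 79 without treated replicate 1, 2 or 3, and 121 or 118 without control replicate 1 or 3. With a correction for gene length and GC content, chosen after control replicate 2 was seen to stand apart, 210 genes were higher and 162 lower.

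**Figure D1:**
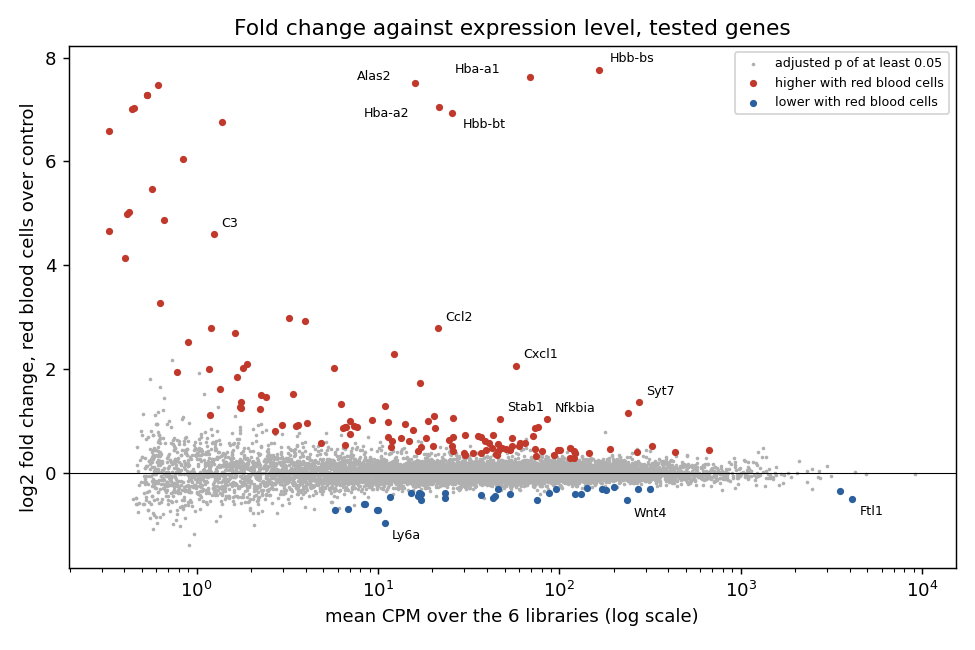
Log2 fold change of red blood cell-treated over control libraries (vertical axis) against the mean CPM of the 6 libraries (horizontal axis, log scale) for the 11208 tested genes, one point per gene. Red points are the 130 genes called higher, blue points the 34 called lower and grey points the rest; the globins and Alas2 lie above 6.9 and no blue point lies below -0.97. Points above 6 at under 1 CPM include genes with 0 counts in the controls, whose fitted value is no bound.

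Chemokine genes rose together. Of the 10 tested members of the list of inflammatory cytokines and chemokines, 7 were called higher and the 3 others had positive fold changes (median log2 fold change 1.77). Adjusted over the list alone, all 10 were higher. The monocyte attractant Ccl2 rose from 5.42 ± 0.18 to 37.4 ± 1.54 CPM (SD, n = 3; log2 fold change 2.79 ± 0.08 SE), and its neighbour in function Ccl7 rose 4.86-fold. The neutrophil attractants Cxcl1 and Cxcl5 rose 4.18-fold (from 22.4 ± 1.33 to 93.5 ± 4.63 CPM) and 3.31-fold. Cx3cl1, Cxcl10 and Lif, the other called members, rose by 0.94, 2.01 and 0.86 on the log2 scale; they were chosen after their values were seen. There were 12 called members without control replicate 2, more than the 10 tested with 6 libraries, because the low-count filter was rerun and kept 11297 genes. Lif lost its call without control replicate 3 or without any one of the treated libraries (log2 fold change between 0.75 and 1.03 with a library left out), and the other 6 kept theirs with each library left out. Tnf and Il1b, too low to be tested, had 1 count each over the controls and 36 and 34 over the treated libraries, ratios of 35.4 (95% interval 5.97 to 1438) and 33.5 (5.61 to 1360.3). The leukocyte marker Ptprc had 0 and 36 counts, so RNA of added white cells stays open as their source.

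Genes that NF-kB induces and that feed back on it rose as well. All 14 tested members of that list had positive fold changes, 6 were called higher and none lower (median 0.66), and 12 were higher when adjusted over the list alone. The inhibitor Nfkbia rose from 56.6 ± 3.78 to 115 ± 2.70 CPM, Traf1, an adaptor of TNF receptors, rose 4.06-fold, and the subunits Relb and Nfkb2 rose 2.09-fold and 1.81-fold. Tnip1 and Tnfaip3, the remaining calls and chosen after their values were seen, rose by 0.58 and 0.34 on the log2 scale. Tnfaip3 lost its call without control replicate 3 or any one treated library, and the other 5 kept theirs with each library left out. There were 9 called members without control replicate 2. In camera's competitive test both the chemokine and the NF-kB list passed (adjusted p = 9.9e-100 and 2.9e-32 with a preset correlation of 0.01). With an estimated correlation their adjusted p was 0.0018 and 0.0023.

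Complement and antigen presentation genes moved in the same direction. In the list of complement and acute phase genes 4 of 5 tested members were called higher (also 4 adjusted over the list alone; median 1.29). The median was 2.14 and 2.28 without control replicate 1 and 2, and 0.84 without treated replicate 2. The low-count filter was rerun in each of these fits, so a median can move because other members were tested. The central component C3 rose from 5 to 131 counts over the 3 libraries (log2 fold change 4.59 ± 0.42 SE; 5.28 without control replicate 1 and 4.02 without control replicate 2), the iron-binding protein Lcn2 from 6 to 62 counts (3.27 ± 0.42), C1s1 from 6.32 ± 0.09 to 15.5 ± 0.40 CPM, and C1ra 1.31-fold. C1ra lost its call without control replicate 3 or without any one treated library (log2 fold change between 0.35 and 0.43). Among 8 tested antigen presentation genes all had positive fold changes and 2 were called higher, also 2 adjusted over the list alone. These were Tapbp, the peptide-loading chaperone tapasin (54.1 ± 3.47 to 88.6 ± 3.47 CPM), and Cd74, the invariant chain of class II molecules, which had 0 counts in the controls and 67 in the treated libraries, at least 22.0-fold higher against a floor of 3 counts over the group. With Cd74 at this bound the median of the list was 0.18, as with its fitted value. Both lists passed camera (adjusted p = 5.4e-19 and 4.6e-06), with adjusted p = 0.0048 and 0.037 with an estimated correlation. With a library left out the latter lay between 0.041 and 0.30. In each list 5 members were called higher without control replicate 2.

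Transcripts of blood cells were higher in the same 3 libraries in which these immune genes were higher. Of the 6 tested members of the erythroid list 5 were called higher, also 5 adjusted over the list alone (median 7.28; camera adjusted p with an estimated correlation 0.00037). Hba-a1 went from 0.69 ± 0.15 to 138 ± 5.91 CPM, Hbb-bs from 1.52 ± 0.20 to 331 ± 29.6 CPM and Alas2 from 0.17 ± 0.05 to 31.8 ± 3.54 CPM. Bpgm, the sixth, had 39.0 ± 2.44 and 42.1 ± 0.35 CPM. Of the leukocyte list 2 of 4 tested members were called higher, also 2 adjusted over the list alone: Ptprc, the pan-leukocyte antigen CD45, with 0 counts in the controls and 36 in the treated libraries (at least 11.8-fold higher), and lysozyme Lyz2 with 14 and 83 counts. Both calls were lost without treated replicate 1 or 2, and without control replicate 2 there were 4. The median of the list, 1.28, was 2.30, 2.11 and 2.73 without control replicate 1, 2 and 3, and 2.81 without treated replicate 3. The 4 calls and these medians can rest on members not tested with 6 libraries, since the low-count filter was rerun in each fit. The list passed camera (adjusted p = 0.00068) but not with an estimated correlation (adjusted p = 0.22) or with a filter at 1 CPM in 3 libraries (adjusted p = 0.062, median 0.05). Without a low-count filter it passed camera with the preset correlation (adjusted p = 3.4e-13) and with an estimated one (0.036). Its median was then 2.59, with 3 members called higher. The members with the highest levels, Csf1r, Cd68 and Lyz2, had 24.7 ± 1.53, 21.2 ± 0.80 and 1.53 ± 0.41 CPM in the treated libraries. Among the platelet markers, of which 2 were tested, Ppbp had 29 and 62 counts and was higher adjusted over the list alone only.

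**Figure D2:**
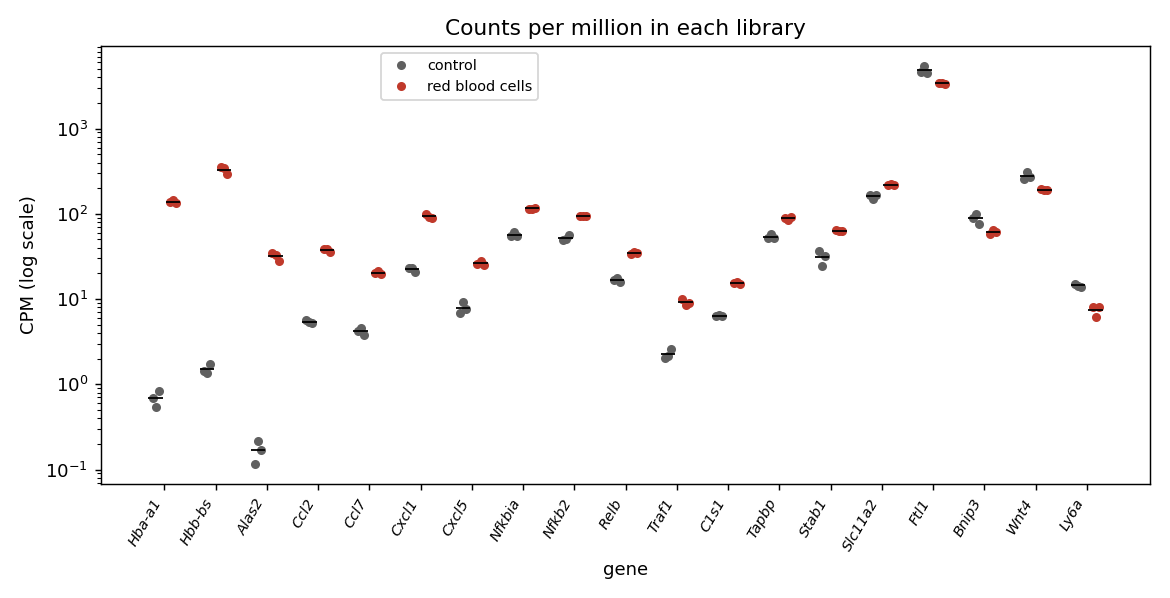
CPM (vertical axis, log scale) of 19 genes in each of the 3 control (grey) and 3 red blood cell-treated (red) libraries, one point per library with a line at the mean of the group. The globins and Alas2 span about 2 orders of magnitude between the groups, Ccl2 lies near 5.42 against 37.4 CPM, and the falls of Ftl1, Bnip3, Wnt4 and Ly6a are each under 2-fold.

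The genes that fell did so by small amounts. The largest fall among those of at least 10 CPM was that of Ly6a, the surface antigen Sca-1, from 14.4 ± 0.56 to 7.37 ± 1.09 CPM (log2 fold change -0.97 ± 0.11 SE). Spns2, the exporter of sphingosine-1-phosphate from endothelial cells, fell from 12.5 ± 0.13 to 7.53 ± 0.60 CPM (-0.73 ± 0.09). Wnt4, a secreted signalling protein, fell from 278 ± 24.7 to 192 ± 1.23 CPM (-0.53 ± 0.07) and the mitophagy receptor Bnip3 from 88.7 ± 11.99 to 61.5 ± 3.28 CPM (-0.53 ± 0.10). Prelp, Ftl1, Ier5l, Pxdc1, Fhl1, Gsta4, Cadm1 and Depdc7 completed the 12 largest falls, with log2 fold changes from -0.53 to -0.44. Aspa (-0.72) and Myh14 (-0.72) were among the 5 with the smallest p. All 14 kept their call without control replicate 2, and only Ly6a and Spns2 kept it with each of the 6 libraries left out in turn; the other 12 lost it without at least 1 treated or control library, while their sign held.

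Genes of glycolysis and the hypoxia response were lower as a list. Of 16 tested members 12 had negative fold changes and 2 were called lower (median -0.22), Bnip3 and P4ha1, the collagen prolyl hydroxylase (-0.29 ± 0.06 SE). Adjusted over the list alone 10 were lower and 1 was higher. Ldha had 2762 ± 254 CPM in the controls and 2212 ± 24.5 CPM in the treated libraries and Pdk1 166 ± 2.96 and 138 ± 5.38 CPM, neither past the threshold over all genes. The list passed camera (adjusted p = 6.7e-05), but with an estimated correlation the adjusted p was 0.22. Both calls were lost without control replicate 1 or any one treated library. Without control replicate 2, 10 members were called lower and 1 higher (median -0.16), and the adjusted p with an estimated correlation was 0.041.

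Genes of the antioxidant response under NRF2 were also lower on balance. Of 18 tested members 15 had negative fold changes and 1 was called lower, the glutathione transferase Gsta4 (51.2 ± 4.77 to 37.5 ± 1.77 CPM). Adjusted over the list alone 8 were lower and 1 higher. Gstm1 and Nqo1 had log2 fold changes of -0.26 and -0.26, and Slc7a11, the cystine transporter, had 0.49, none past the threshold over all genes. Camera gave an adjusted p of 0.00081, which was 0.22 with an estimated correlation. Without control replicate 2, 10 members were called lower and 1 higher, and the adjusted p with an estimated correlation was 0.11. The Gsta4 call was lost without control replicate 3 or any one treated library.

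Heme and iron handling genes went both ways, with 2 of 17 tested members called higher and 1 lower, and 2 higher and 4 lower adjusted over the list alone. The ferritin light chain Ftl1, whose reads pseudogene copies can share, fell from 4841 ± 527 to 3410 ± 66.9 CPM, and the heavy chain Fth1 had 878 ± 92.8 and 697 ± 31.5 CPM without a call. The iron importer Slc11a2 rose from 161 ± 10.03 to 221 ± 2.77 CPM and the ferroxidase Cp from 52.2 ± 4.23 to 77.1 ± 4.22 CPM. Heme oxygenase Hmox1, which breaks heme down, had 109 ± 5.11 and 93.0 ± 2.74 CPM, and the transferrin receptor Tfrc 313 ± 2.86 and 278 ± 7.45 CPM; neither was called, and both were chosen after their values were seen. The list did not pass camera (adjusted p = 0.32), while fry, which does not compare it with other genes, gave an adjusted p of 0.030. Ftl1 and Slc11a2 lost their calls without any one treated library, and Cp without treated replicate 2 or 3. Leaving out control replicate 2 gave 2 higher and 5 lower members. Fth1, Hmox1 and Tfrc were among the lower ones, with log2 fold changes of -0.24, -0.20 and -0.16 in that fit.

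**Figure D3:**
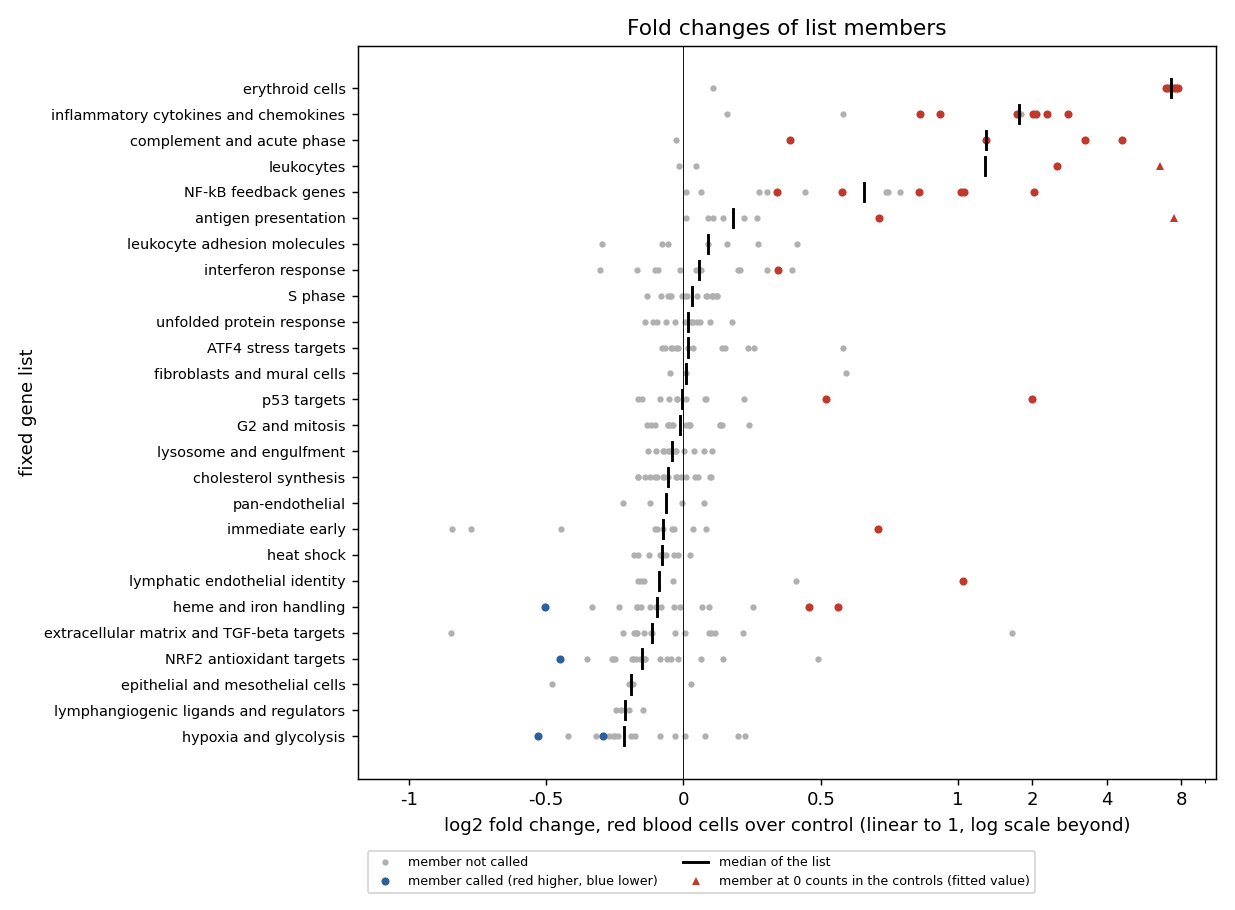
Log2 fold changes of the tested members (points) of the 26 gene lists that could be tested, on a horizontal axis that is linear to 1 and logarithmic beyond, with a black bar at each list's median. Red and blue points are members called higher or lower, grey points are not called, and triangles are members with 0 counts in the controls. The medians run from 7.28 for erythroid cells and 1.77 for chemokines to -0.22 for hypoxia and glycolysis.

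Members were called in 4 further lists that did not pass camera, 2 among the p53 targets and 1 in each of the others. Stab1, a scavenger receptor of lymphatic and sinusoidal endothelium, rose from 30.9 ± 5.86 to 63.5 ± 0.50 CPM, the 1 call among 6 tested markers of lymphatic endothelial identity (2 higher and 1 lower adjusted over the list alone). That list's median was -0.09 and its mean 0.16. Nrp2 had a log2 fold change of 0.41 ± 0.12 SE without a call. Without control replicate 2 that of Nrp2 was 0.26, with a call, and that of Stab1 was 0.90 against 1.04 with 6 libraries. Among 12 p53 targets Plk2 rose 1.43-fold and the death receptor Fas 3.97-fold (25 to 102 counts; also 2 adjusted over the list alone), and the Fas call was lost without treated replicate 2. The 1 call among 12 interferon response genes was Irf1 (1.27-fold; 2 higher adjusted over the list alone), lost without any one library other than control replicate 2, and the 1 call among 11 immediate early genes was Junb (27.1 ± 1.09 to 44.2 ± 2.91 CPM; also 1 adjusted over the list alone). Fos and Fosb had log2 fold changes of -0.77 and -0.84 on 23 to 92 counts per group, without a call.

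No member was called in the remaining lists by edgeR with the 6 libraries and the low-count filter; without the filter 1 fibroblast marker was called higher. DESeq2 called 1 fibroblast marker higher and 1 epithelial marker lower in them, and voom without library weights called none. With library weights voom called 2 adhesion genes, 2 ATF4 targets, 1 matrix gene and 1 fibroblast marker higher, and 5 matrix, 2 cholesterol, 2 epithelial and 1 heat shock gene lower. The length and GC correction called 1 ATF4 target and 1 fibroblast marker higher, and 3 matrix, 2 epithelial and 1 cholesterol gene lower. In edgeR 1 epithelial marker was lower without control replicate 1. For the pan-endothelial, heat shock, unfolded protein response, S phase, G2 and mitosis, cholesterol synthesis, lysosome and engulfment, and lymphangiogenic lists, 0 members passed adjusted over the list alone either. Adjusted over the list alone the leukocyte adhesion genes Selp and Vcam1 (log2 fold changes 0.41 and 0.27), 1 ATF4 target, 1 matrix or TGF-beta target and 1 fibroblast marker were higher, and 2 epithelial markers were lower. The epithelial and mesothelial list passed camera downward (adjusted p = 0.043; 0.39 with an estimated correlation) with Krt18 at 44.8 ± 7.32 and 32.1 ± 0.64 CPM, and this was lost without treated replicate 2 or 3 (adjusted p = 0.10 and 0.091) and without a low-count filter (0.057). The mean and the median differed in sign for the p53, G2 and mitosis, matrix and lymphatic identity lists. None of the 13 transcripts of the mitochondrial genome is listed in the tables used here. In all, 9 of 26 lists passed camera and 5 passed with an estimated correlation: erythroid, chemokine, NF-kB, complement and antigen presentation. In the other 17 the adjusted p of camera lay between 0.16 and 0.88. Without control replicate 2, 14 passed, the 5 added being matrix and TGF-beta targets (8 members called lower and 2 higher, adjusted p = 0.0016), S phase (5 higher, 0.037), ATF4 targets (3 higher, 0.044), lymphatic identity (2 higher and 1 lower, 0.031) and heme and iron handling (0.044). With an estimated correlation none of these 5 passed. In the same fit 2 adhesion genes, 1 unfolded protein response gene and 1 fibroblast marker were called higher, and 2 cholesterol genes, 2 epithelial markers, 1 heat shock gene and 1 fibroblast marker lower.

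The deposited FPKM values gave nearly the same ranking of genes. Across 9968 genes tested in both, which are not independent replicates, the log2 fold changes from limma on log2(FPKM + 1) and from the counts had a Spearman rho of 0.996 and a Pearson r of 0.95. On that scale, which understates the change of low genes, 131 genes were called, 102 higher and 29 lower.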

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

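Library weights and the length and GC offset were chosen after control replicate 2 was seen to stand apart; the other alternatives were planned. No called gene changed sign under any of them. RLE scaling, no scaling, voom and no filter gave 161 to 198 changed genes, near the 164 of the reported test, and leaving out the erythroid genes or filtering at 1 CPM gave 157 and 147. DESeq2 called 236, of which 67 were lower, against 34. With an estimated correlation camera passed 5 lists instead of 9, and fry passed 10. The replicate number as a block left 126 changed genes, 13 of them lower. Deviations of libraries with the same number had an r of -0.01 to 0.06, against -0.07 to 0.04 for different numbers. Values this small cannot settle whether the numbers pair the libraries.

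With single libraries left out, changed genes ranged from 62 (without treated replicate 2) to 899 (without control replicate 2), higher genes from 60 to 473, lower genes from 2 to 426, genes changed at least 2-fold from 39 to 85, and lists from 8 to 14. All 164 calls were kept without control replicate 2, 114 and 112 without control replicates 1 and 3, and 69, 62 and 76 without treated replicates 1 to 3. Fewer libraries lower the power, but without control replicate 2 the spread within controls also falls. Library weights, which gave that library 0.12 against 1.20 to 1.86, called 651 genes (362 higher, 289 lower) and 14 lists, and the length and GC offset 372 genes (210 higher, 162 lower) and 9 lists. The share of higher genes, 130 of 164, was 52.6% without control replicate 2, 55.6% with library weights and 56.5% with the offset. It was 86.8% and 90.7% without control replicates 1 and 3, and 97.2%, 96.8% and 96.2% without treated replicates 1 to 3, so the excess of rises over falls at the threshold changes with the libraries used. In simulated counts 3.68% of calls were false with 6 libraries and 8.37% without control replicate 2. No simulated library was made to stand apart, so these shares do not describe the effect of leaving out the real one.

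On FPKM, 21 genes changed at least 2-fold with a pseudocount of 1, with or without a filter, and 31 with 0.1; the pseudocount shrinks the folds of low genes. The correlation across genes of both files' log2 fold changes, 0.95, was 0.99 with a pseudocount of 0.1, 0.75 without a filter, and 0.91 to 0.95 with a library left out.

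Medians near 0 of lists that were not called changed sign in 2 to 5 lists when a library was left out, in 3 with library weights, and in 2 each with the offset and without a filter. Folds of Csf1r, Des, Eng, Flt1, Egfl7 and Gp1bb, near 0 and not called, also changed sign under some settings, so no fold is given for them; the cause was not tested. Camera lost the leukocyte list with a filter at 1 CPM (adjusted p = 0.062), which tests fewer genes, and the epithelial list without a filter (0.057). Depth limits genes near 0.056 CPM and, with the spread of these libraries, small changes: 41.8% of the smallest simulated changes and 88.1% of those of 1.5-fold were called. The simulated libraries held none that stood apart as control replicate 2 does.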

Other observations

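Every gene in this first part was chosen after its values were seen. Beyond the listed chemokines, Cxcl3 rose from 0.73 to 5.78 CPM (log2 fold change 2.98 ± 0.18 SE), Enpp2, which makes lysophosphatidic acid, from 0.91 to 6.99 CPM (2.92 ± 0.18), and the inducible nitric oxide synthase Nos2 from 23 to 153 counts over the 3 libraries (2.69 ± 0.24). Cyp26b1, which breaks down retinoic acid, rose from 13.02 to 27.8 CPM (1.09 ± 0.09), Tmem176b from 53.9 to 99.6 CPM (0.89 ± 0.06), the protease inhibitor Slpi from 7.70 to 15.2 CPM (0.98 ± 0.09) and the TNF receptor family member Tnfrsf9 from 3.59 to 8.96 CPM (1.32 ± 0.11). These 7 genes kept their calls in edgeR with each library left out. Lower were the prostaglandin synthase Ptgs2 (300 to 241 CPM, -0.31 ± 0.05), Vim, the intermediate filament of mesenchymal cells (3959.9 to 3089 CPM, -0.36 ± 0.07) and Spp1 (99.8 to 76.1 CPM, -0.39 ± 0.08). Each of these 3 lost its call without any one library other than control replicate 2. Of the 130 genes called higher, 24 had a control mean under 0.5 CPM. Among them were the macrophage genes Adgre1 and Cybb, at 0 counts in the controls and 48 and 58 in the treated libraries (at least 15.7-fold and 19.0-fold higher), Mpeg1 with 1 and 91 counts (ratio 89.6, 95% interval 15.7 to 3576) and Ccl3 with 2 and 70 counts (34.5, 9.19 to 290.1). The Cybb call was lost without treated replicate 1 or 2.

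The tests in the paragraphs that follow were in part chosen only after the result was seen: those of length bias in control replicate 2, of blood RNA and of globin expression, and of white cell RNA and control replicate 2 as sources of the chemokine rise. The tests of hypoxia genes, of the whole length and GC trend, of depth and of other splits were written before their results were seen.

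A hypothesis from the lower glycolysis and hypoxia genes is that targets of hypoxia signalling fell together. A second list of 17 such genes, none of them in the first, was written before their values were looked up. Of the 16 tested, 15 had negative fold changes (median -0.14; camera p = 2.8e-06, and p = 0.030 with an estimated correlation) and 0 were called in edgeR over all genes. Without control replicate 2 all 16 were negative, 11 were called lower and the median was -0.12 (p = 1.0e-08, and 0.0087 with an estimated correlation), among them Tpi1 (-0.23 ± 0.03 SE) and Pgam1 (-0.21 ± 0.03). With the length and GC correction the median was -0.18. These values go with the hypothesis, though the changes are small. Many of the members called lower without control replicate 2 are glycolysis enzymes, beside Ak4, Bnip3l, Higd1a and Mif. Egln1, Ero1a, Gbe1, Kdm3a and Mxi1 were not called in that fit. A fall of mainly glycolysis genes therefore stays open. Whether oxygen, heme or another signal is behind it was not tested.

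Control replicate 2 stands apart from the other libraries, and the labels give no group difference for it, so no biological explanation was tested. Its deviation from the mean of the other controls fell with gene model length (Spearman rho -0.68 across 10792 genes, against 0.11 for the difference of the other controls). The test had set 0.1 as the limit for the other controls, which 0.11 narrowly missed, so it is undecided by that limit, itself set after the result was seen. The treated mean minus the mean of control replicates 1 and 3 had a rho of -0.05 with length. A trend of the size seen in control replicate 2 was thus absent from both comparisons without it. The origin of that trend stays open. The median deviation on the log2 scale was 0.24 in a group of short genes (median length 1377 bases) and -0.28 in a group of long ones (8934 bases). A loss of reads of long transcripts in this library may account for part of it. Across the 8863 genes of at least 10 CPM the trend with length and GC content held 56.2% of the variance of the deviations, and after it was removed their SD was still 2.13 times that expected from the other controls, which argues against this trend as the whole cause. After thinning to the total of control replicate 1 the chi-square per gene was 27.4. That test says nothing on deeper sequencing: the chi-square already allows for the totals, and these were close (18381419 against 17263359). What makes up the rest, such as RNA quality or a different culture, stays open.

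Globin and leukocyte transcripts appeared in all 3 treated libraries. Of the 12 listed leukocyte markers under 0.5 CPM in the controls, 8 lay above every control in each treated library. Since the rise of these transcripts is the pattern itself, this count does not decide where they came from. RNA carried in with the added blood cells and globin expression switched on in the cultured cells cannot be told apart, since red blood cells were added to every treated library and to none of the controls. The erythroid regulators Klf1 and Gata1 had 21 counts in the controls and 14 in the treated libraries, too few to decide.

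The rise of chemokine and NF-kB genes was seen in the same libraries as these white cell transcripts. RNA of white cells is argued against as the source of the rise of the 13 called members as a set: the largest gain among the low-baseline leukocyte markers, 1.27 CPM for Lyz2, was 7.77% of the members' median gain of 16.3 CPM. This holds only if the white cells carried no more of these transcripts than of such markers, which was not measured. For members with small gains, such as Cxcl10 (2.18 CPM), Lif (3.68 CPM) and Traf1 (6.93 CPM), white cell RNA stays open, since Mpeg1, a macrophage gene outside that list, gained more than Lyz2. It also stays open for Tnf, Il1b, Lcn2 and Cd74, with 36, 34, 62 and 67 counts over the treated libraries. Ptprc and Lyz2 had 36 and 83 counts there. All 13 called members were still called without control replicate 2, but so were all 164 called genes, so this count decides nothing. Their log2 fold changes stayed near the same without that library, which argues against it as the cause. That of Ccl2 went from 2.79 to 2.78, that of Lif, which fell most, from 0.86 to 0.75, and that of Cxcl5 rose from 1.73 to 1.85. Signals released by white cells, heme or other contents of the preparation remain possible explanations, since no library analysed here separates them. Among the heme and iron genes, Hmox1 (log2 fold change -0.23, not called) and Ftl1 (-0.50, called) did not rise, while Slc11a2 (0.46) and Cp (0.56) did. Without control replicate 2 Hmox1 was called lower (-0.20). These values do not decide on heme, since no library was given heme alone.

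Among the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) called as many as 164 genes in edgeR, and the highest other count was 0. For the lists past camera it was also 1 of 10, with 9 in the real split and 8 in the highest other. Camera with the preset correlation thus passed lists in splits that mixed the groups and called 0 genes. Passing it is by itself weak evidence of a difference between the groups. With 10 splits a share under 0.05 cannot be reached.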
